A study of Homo sapiens with 6 samples.

How the data were processed

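RNA was measured in 6 cultures grown from human glioblastoma, a malignant brain tumour, and labelled as endothelial cells. Per the labels' protocols, the cells were kept in endothelial medium with VEGF-A, transduced with a lentivirus carrying Cas9 and a guide RNA, and selected with puromycin. There were 3 libraries with a control guide and 3 with a guide against PHGDH, the first enzyme of serine synthesis. Each title holds a number shared by 1 library of each guide. No label explains the number, which was read here as the tumour of origin, and the 3 pairs are called line 1, line 2 and line 3. Ribosomal RNA was depleted before paired-end sequencing, per the labels' protocols.

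The authors deposited a table of estimated counts per gene symbol for 19681 genes, not scaled to library size as far as its totals show. Kallisto 0.46.1, R 4.0.5, edgeR 3.36.0 and the genome build GRCh38 are named in the submitters' processing notes, without saying which step each served. How transcript estimates were added up to genes, and whether the library kit's strand was used, is not given in the sources used here. The reads of overlapping genes and of near-identical copies, such as histone and metallothionein genes, may therefore be divided by the quantifier's model, and their values are uncertain to that extent. Between 3.74% and 6.22% of a library's values were not whole (tolerance 1e-06), and all values were rounded to whole numbers for the count tests. Of 15583 genes with reads in every line, 0 held a value above 1 that was not whole, whereas 2047 of 2375 genes with 1 or 2 lines at 0 in both libraries did. The deposited table is named as raw counts, and no label or file header says how these 2 kinds of genes arose.

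Library totals were 13254285, 13370560 and 4891597 counts for the control guide in lines 1 to 3, and 13061219, 12777108 and 12710215 for the PHGDH guide. A count of 3 corresponds to between 0.224 and 0.613 CPM, the usual scaling of counts to library size. Intervals and floors cover counting error only. Control line 3, the shallowest library, has the least precise values for low genes. No 2 libraries agreed within sampling noise, as the chi-square statistic per degree of freedom between libraries lay between 12.1 and 40.8 over genes with 20 or more counts.

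The main comparison used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, a robust quasi-likelihood fit of guide alone, and Benjamini-Hochberg adjusted p under 0.05. The filter kept 13822 genes and removed 5859. Standard errors (SE) are the log2 fold change over the square root of its F statistic. Values per library are TMM-scaled CPM. Log2 ratios within a line are on log2 CPM with a prior count of 2. The 30 gene lists, with 707 of 713 symbols found, 46 of them by an older symbol in the RefSeq gene table, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. Only lists with 5 or more tested genes entered, which left 29, since the lymphocyte list had 3. The p-values of this fit rest on the spread of the 6 libraries around their guide means and leave out the pairing by line. They may be too small, as described under other observations. They were not shown to measure the spread between independent cultures.

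The named genes followed a rule fixed before the data were examined: PHGDH, then up to 12 genes each way past the threshold with the same sign in every line and a mean log2 CPM of at least 1 (0 passed in edgeR, with or without the line block), then up to 4 tested members of each list with the smallest p, and every member of the serine synthesis list. SDS, a member of that list, did not pass the filter. SLC7A2, KCTD7, BDKRB2, GEM, FAT4, TMTC2, FLCN, CRCP, RABGEF1, MKI67, CXCL8, MX1, HIST1H1D, FN1, KRT6A, KRT16, S100A9, MT1E, MT2A and the cell type markers given by level alone (PECAM1, VWF, CDH5, KDR, TEK, COL1A2, DCN, THY1, CSPG4, PDGFRB, NES) lie outside that rule and were chosen after their values were seen. XIST and Y-linked genes were left out of all gene tables.

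The shared title number, read as the tumour of origin, pairs the libraries. Deviations from the guide means were compared between the libraries of each line. Their correlation across genes was -0.72, -0.74 and -0.64 in lines 1 to 3 over 13719 tested genes with reads in every line. It was 0.932, 0.918 and 0.874 over 103 tested genes with 1 or 2 lines at 0, but these were picked for being at 0 in both libraries of a line. The pairing therefore rests on the title number and not on this check. The fit with the line as a block (replicate block) was planned as an alternative.

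Alternatives were DESeq2 1.42.0 and limma-voom with and without the block, DESeq2 size factors, library totals, no filter, a stricter filter of 1 CPM in 3 libraries, 2 other thresholds, fry, camera with an estimated correlation, and leaving out each line or library. On counts simulated from these libraries with 200 changed genes (13502 genes tested), edgeR without the block recovered 7.46% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 89.2% of those changed 4-fold. There were 7 false calls in edgeR without the block, 14 with it and 52 in DESeq2 without the block. These counts came from 1 draw without line effects or a correction by line, and the changed genes had an average log2 CPM above 1. The recovered shares may not hold for the deposited values. An absence of calls therefore does not show that such changes are absent. Line effects were simulated apart from this and corrected with ComBat-seq (sva 3.50.0). Gene positions come from GENCODE 29 on GRCh38.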

Results

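The series asked how loss of PHGDH changes gene expression in cells labelled as endothelial and grown from glioblastoma. Expression was measured by RNA sequencing in 6 cultures, 3 with a control guide and 3 with a guide against PHGDH. Each of 3 lines contributed 1 culture per guide. Library totals ran from 4891597 counts (control line 3) to 13370560 counts (control line 2), and 13822 of 19681 genes were tested.

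PHGDH RNA was lower under the PHGDH guide in all 3 lines. The control-guide libraries had 9.66 ± 6.34 CPM (SD, n = 3) and the PHGDH-guide libraries 0.847 ± 0.609 CPM (SD, n = 3). The level was 7.93 against 1.07 CPM in line 1, 16.7 against 0.157 CPM in line 2 and 4.37 against 1.31 CPM in line 3. The share left was 13.5%, 0.939% and 30%. These values rest on 105, 222 and 21 counts under the control guide and 14, 2 and 17 counts under the PHGDH guide. In line 3 the 95% Poisson intervals were 2.71 to 6.68 CPM and 0.763 to 2.1 CPM, which do not overlap.

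The log2 fold change of PHGDH was -3.52 ± 0.77 (SE). Its adjusted p was 0.178 over all genes tested with edgeR and 0.0282 when adjusted over the list alone, that of serine synthesis. With the replicate block the p adjusted over the list alone was 0.0878. Over all genes, the DESeq2 adjusted p of PHGDH was 5.556e-04 without the block and 0.0709 with it. The 20-base guide GGAGGCCGACAATGACTGCG, from the labels' cloning sequence, matched PHGDH and no other gene among the annotated transcripts. Its site lies on chromosome 1 from 119741804 to 119741823 (GRCh38) on the minus strand, beside a GGG motif, in the coding part of exon 10 in most coding transcripts of the gene, which spans 119648411 to 119744226. A frameshift there need not remove the RNA, so the RNA level tests the edit only in part.

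**Figure D1:**
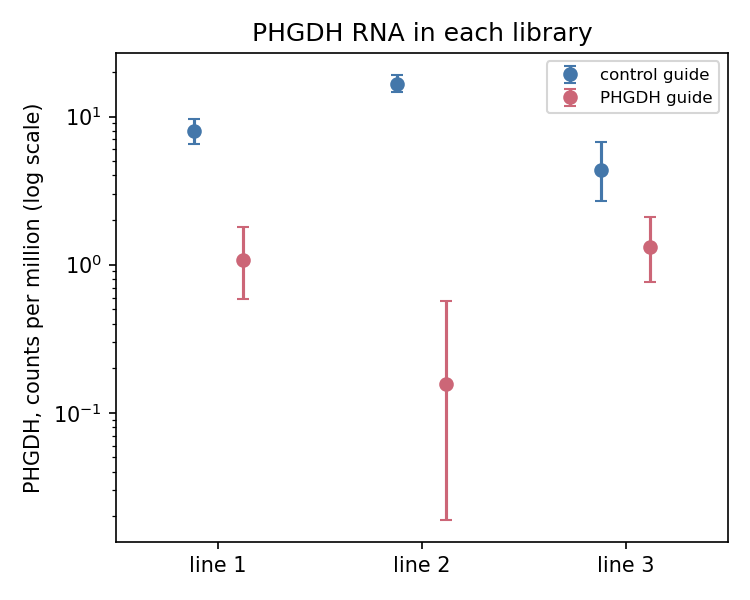
PHGDH in CPM on a log axis, for the control guide and the PHGDH guide in lines 1 to 3. Bars are 95% Poisson intervals from the counts. In each line the PHGDH-guide library lies below its control, with 13.5%, 0.939% and 30% of the level left.

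The enzymes that act beside PHGDH did not pass the test. PSAT1, the second enzyme of serine synthesis, had 35.4 ± 9.13 CPM with the control guide and 29.5 ± 9.26 CPM with the PHGDH guide (SD, n = 3). PSPH, the third, had 17.5 ± 2.30 and 20.9 ± 2.40 CPM. SHMT2, which passes serine carbon into the mitochondrial folate cycle, had 89.8 ± 21.4 and 74.7 ± 18.4 CPM, and SHMT1 13.8 ± 1.43 and 13.9 ± 1.25 CPM. SRR, which makes D-serine, had 16.9 ± 1.13 and 20.8 ± 1.25 CPM (adjusted p = 0.0645 in edgeR, adjusted over the list alone), and SDSL 5.87 ± 0.97 and 5.78 ± 0.52 CPM. Of 7 tested members of the serine synthesis list, 1 passed when adjusted over the list alone, PHGDH itself. The list was not called by camera (adjusted p = 0.895).

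No gene passed an adjusted p of 0.05 over all genes tested in edgeR, with 0 calls without the block and 0 with the replicate block. An unadjusted p under 0.05 was reached by 2028 genes without the block (980 higher, 1048 lower), and by 385 with it. A uniform null gives 691, but the 3 other splits of the libraries that also part all 3 pairs gave 1878 to 2604 such genes without the block, so 2028 is no excess over them. DESeq2 called 223 genes without the block (97 higher, 126 lower) and 3 with it. limma-voom called 2 without and 0 with the block. The call of a gene therefore depended on the tool and on the block.

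The genes nearest to the threshold were picked for their small p, which favours genes with little spread between libraries. SLC7A2, a transporter of arginine and lysine (chromosome 8, 17497088 to 17570573), had 159 ± 7.63 CPM with the control guide and 306.5 ± 14.6 CPM with the PHGDH guide (SD, n = 3). Its log2 fold change was 0.95 ± 0.06 (SE), with adjusted p = 0.0649 in edgeR, 0.000143 in DESeq2 with the replicate block and 0.043 in limma-voom without it. BDKRB2, the bradykinin receptor, had 50 ± 1.16 and 82.7 ± 2.30 CPM (adjusted p = 0.0756). GEM, a small GTP-binding protein, had 50.9 ± 1.03 and 78.7 ± 1.22 CPM, and TMTC2 2.30 ± 0.43 and 10.3 ± 1.28 CPM (adjusted p = 0.0917 for both). FAT4, a large cadherin, had 169 ± 7.58 and 105 ± 4.64 CPM (adjusted p = 0.0917). FLCN, the folliculin gene, had a log2 fold change of 0.69 ± 0.07 (SE) with adjusted p = 0.111.

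THBS1, which encodes thrombospondin 1, a secreted inhibitor of angiogenesis (chromosome 15, 39581079 to 39599466), had 733 ± 52.3 CPM with the control guide and 417 ± 32.1 CPM with the PHGDH guide (SD, n = 3). Its log2 fold change was -0.81 ± 0.09 (SE), with log2 ratios of -0.75, -0.64 and -1.05 in lines 1 to 3. Its adjusted p was 0.111 over all genes in edgeR and 0.00974 in DESeq2 with the replicate block. KCTD7 (chromosome 7, 66628767 to 66649067) was at 0 counts in the 3 control-guide libraries and at 9.67, 9.64 and 9.33 CPM with the PHGDH guide. Against a floor of 3 counts over the control group, 0.0957 CPM, it was at least 99.7-fold higher. Its adjusted p was 0.0649 in edgeR and 2.65e-07 in DESeq2 with the replicate block. An annotated read-through gene (66628958 to 66811189) overlaps KCTD7 and its neighbour RABGEF1, so its reads cannot be assigned with certainty.

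**Figure D2:**
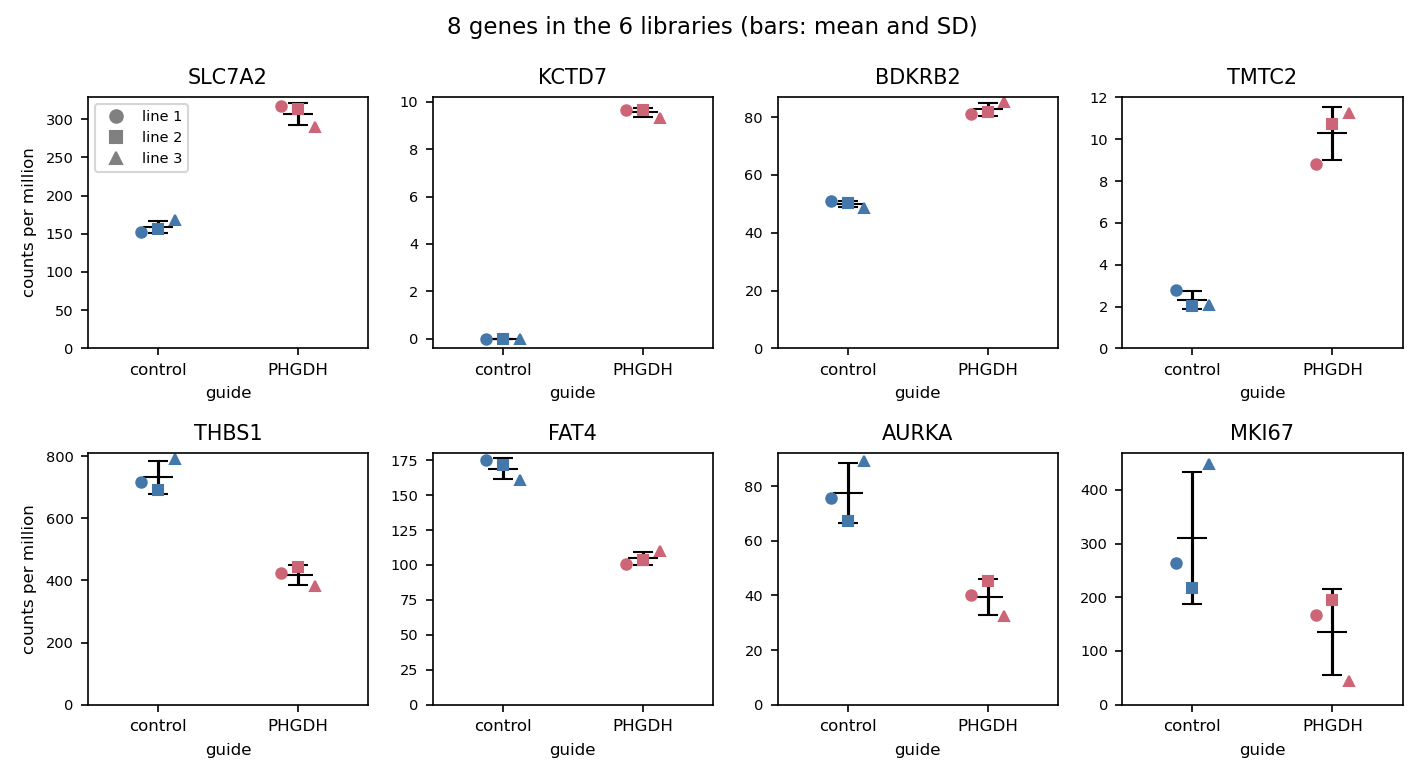
CPM of 8 genes in the 6 libraries, by guide, with lines 1 to 3 as circles, squares and triangles. Horizontal marks and bars are the mean and SD of 3 libraries. SLC7A2 lies near 159 CPM with the control guide and 306.5 CPM with the PHGDH guide, while MKI67 is spread most by line 3.

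Genes of cell division were lower under the PHGDH guide as sets, by amounts that differed between lines. Of 33 mitosis and G2/M genes, 25 were lower in all 3 lines and 0 were higher in all 3, with a median log2 fold change of -1.01 (camera adjusted p = 1.2e-11; adjusted p = 0.768 with an estimated correlation). AURKA, a mitotic kinase, fell from 77.6 ± 11.1 to 39.5 ± 6.43 CPM (SD, n = 3), with edgeR adjusted p = 0.0331 adjusted over the list alone, the 1 member that passed there. That p was 0.122 with the replicate block. CCNB1, the mitotic cyclin, had 169 ± 39.6 and 83.4 ± 23.8 CPM, FOXM1, a regulator of mitotic genes, 72.3 ± 12.3 and 44.5 ± 8.43 CPM, and NDC80, a kinetochore gene, 40.5 ± 6.98 and 25.1 ± 4.96 CPM. The list's median log2 ratio was -0.62 in line 1, -0.25 in line 2 and -2.56 in line 3. MKI67, the proliferation marker, stood at 449 against 43.6 CPM in line 3 and at 217 against 196 CPM in line 2.

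Replication-dependent histones, whose RNA is made during S phase, had a median log2 fold change of -0.58 (camera adjusted p = 2.06e-09; adjusted p = 0.724 with an estimated correlation). Their median log2 ratio was -0.53 in line 1, -0.08 in line 2, where 12 of 30 were higher, and -1.16 in line 3. Of 30 members, 17 were lower in all lines. Adjusted over the list alone 5 passed without the block, all lower, and 0 with the replicate block. HIST1H3A fell from 18.9 ± 2.39 to 11.03 ± 1.45 CPM (SD, n = 3) and HIST1H2BH from 13.9 ± 1.47 to 8.31 ± 1.07 CPM. HIST1H2AI, HIST1H1C and HIST1H1D were the other 3. DNA replication and G1/S genes had a median of -0.30 over 29 members (camera adjusted p = 4.05e-06; adjusted p = 0.724 with an estimated correlation), and 0 passed when adjusted over the list alone. Their median log2 ratio was -0.34, 0.01 and -0.58 in lines 1 to 3, so line 2, with 14 lower and 15 higher, showed no fall, and 9 were lower in all lines. MCM7, a helicase subunit, had 57.2 ± 6.46 and 36.9 ± 4.45 CPM, UHRF1 75.2 ± 8.75 and 50.5 ± 6.64 CPM, RFC3 27.1 ± 2.86 and 18.6 ± 2.11 CPM, and PCNA 89.5 ± 8.21 and 67.3 ± 6.26 CPM.

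Nucleotide synthesis genes had a median log2 fold change of -0.12 over 30 members (camera adjusted p = 0.0421; adjusted p = 0.724 with an estimated correlation). RRM1, the large subunit of ribonucleotide reductase, fell from 113 ± 3.55 to 86.5 ± 2.93 CPM (SD, n = 3), with edgeR adjusted p = 0.0157 adjusted over the list alone. DTYMK, which makes dTDP, fell from 54.3 ± 3.98 to 39.8 ± 3.22 CPM with edgeR adjusted p = 0.0484 adjusted over the list alone. For RRM1 and DTYMK alike that p was 0.353 with the replicate block. TK1, the S-phase thymidine kinase, had 51.1 ± 12.4 and 25.9 ± 7.63 CPM and PPAT, the first enzyme committed to purine synthesis, 48.6 ± 1.75 and 58.3 ± 1.91 CPM, and neither passed. The list call was lost when any line was left out, with adjusted p up to 0.166.

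Glycolysis genes had a median of -0.31 over 25 members (camera adjusted p = 0.00402; adjusted p = 0.781 with an estimated correlation). PFKL, the liver-type phosphofructokinase, fell from 157 ± 10.4 to 115 ± 8.30 CPM (SD, n = 3), with edgeR adjusted p = 0.0404 adjusted over the list alone. That p was 0.412 with the replicate block. LDHA had 1420 ± 268 and 938 ± 209 CPM, PKM 2107 ± 112 and 1812 ± 107 CPM, and SLC2A1, a glucose transporter, 42.2 ± 9.95 and 25.8 ± 7.34 CPM. The list's median log2 ratio was -0.11, 0.06 and -0.96 in lines 1 to 3, and the call was lost without line 3 (adjusted p = 0.925) or either of its libraries (up to 0.115). Hypoxia response genes had a median of -0.26 over 20 members, with camera adjusted p = 0.0525 without and 0.0191 with the replicate block (adjusted p = 0.807 with block and an estimated correlation). In that list EPAS1, the HIF-2 alpha gene, rose from 287 ± 16.2 to 398 ± 20.7 CPM, with edgeR adjusted p = 0.0105 adjusted over the list alone. Its value with the replicate block was 0.229.

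The other metabolic and stress lists were not called by camera without the block. The folate one-carbon list had adjusted p = 0.688 over 20 members and the methionine cycle and histone methyl transfer list 0.934 over 28. MTR, methionine synthase and a member of both, had 140 ± 3.86 and 119 ± 3.41 CPM (SD, n = 3). KDM6B, a histone demethylase, had 23.3 ± 2.39 and 34.3 ± 3.504 CPM, and SETD1A, a histone methyltransferase, 15.7 ± 4.13 and 34.2 ± 9.09 CPM. The ATF4 and amino acid response list had a median log2 ratio of 0.72 in line 1, -0.13 in line 2 and -0.07 in line 3 (adjusted p = 0.386). The glutathione and NRF2 list had adjusted p = 0.0525 without and 0.0401 with the replicate block (adjusted p = 0.807 with block and an estimated correlation). Its member SQSTM1, an autophagy receptor, had 943 ± 188 and 1453 ± 257 CPM.

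Cholesterol synthesis had camera adjusted p = 0.12, p53 targets 0.386, the unfolded protein response 0.895 (median 0.04, mean 0.08, test in the lower direction) and nuclear-encoded oxidative phosphorylation 0.972. Members of the p53, unfolded protein response and oxidative phosphorylation lists passed in edgeR without the block when adjusted over the list alone. With the replicate block 0 did. The blocked values were 0.549 for FAS, 0.236 for TP53INP1, 0.522 for SEL1L and PDIA6, and 0.995 for ATP5F1. FAS, a death receptor, fell from 30.7 ± 0.67 to 22.8 ± 0.44 CPM (SD, n = 3), while TP53INP1, another p53 target, rose from 54.5 ± 9.02 to 93.2 ± 13.6 CPM. SEL1L, part of the machinery that removes misfolded proteins, rose from 245.5 ± 10.4 to 308.5 ± 13.9 CPM and PDIA6, a protein disulfide isomerase, fell from 479 ± 16.3 to 398 ± 14.8 CPM. ATP5F1, an ATP synthase subunit, rose from 10.4 ± 0.21 to 15.5 ± 0.28 CPM. These rest on 136, 141 and 49 counts with the control guide and 205, 194 and 203 with the PHGDH guide. Counting error alone would on average give larger SDs than those of ATP5F1 and FAS, and than those of GEM, BDKRB2 and NOTCH4. The SDs of these genes thus understate the spread between cultures. Other SDs given here may do so too. Over 13719 tested genes with reads in every line, the line held 11.5% of the variance, where chance gives 40%.

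Among genes of VEGF response, tip cells and angiogenesis, 2 of 35 passed when adjusted over the list alone, both lower, and the list was not called (camera adjusted p = 0.127). THBS1 was 1 of them, with edgeR adjusted p = 0.00317 adjusted over the list alone. NOTCH4, an endothelial Notch receptor, fell from 4.25 ± 0.32 to 2.32 ± 0.16 CPM (SD, n = 3). NRP1, a VEGF co-receptor, had 768 ± 50.9 and 629 ± 41.0 CPM and did not pass. Of 36 genes of mesenchymal transition and matrix, 2 passed. CTGF, a matricellular gene, fell from 541.5 ± 69.5 to 333 ± 48.0 CPM and TGFBR1 rose from 122 ± 5.56 to 159 ± 7.62 CPM, with camera adjusted p = 0.12 for the list. Across the 30 lists, 20 list members passed when adjusted over the list alone, and 1 did so with the replicate block, THBS1.

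Type I interferon response genes had a median log2 fold change of -0.56 over 28 members (camera adjusted p = 4.9e-04; adjusted p = 0.781 with an estimated correlation). Their median log2 ratio was 0.25 in line 1, 0.08 in line 2 and -2.82 in line 3. MX1, an antiviral GTPase, had 144 against 8.4 CPM in line 3 and 56.5 against 109 CPM in line 1. Without line 3 the direction turned to higher (adjusted p = 0.0822), and without either of its libraries the call was lost (up to 0.302). IRF9 had 10.3 ± 1.27 and 7.02 ± 0.77 CPM (SD, n = 3), and 0 members passed when adjusted over the list alone. The antigen presentation list had adjusted p = 0.516, with a median of 0.01, a mean of -0.02 and a test in the lower direction.

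The adhesion molecules, cytokines and chemokines of endothelium were not called (camera adjusted p = 0.12). Their median log2 ratio was 1.75 in line 1, 0.10 in line 2 and -0.73 in line 3. CXCL8, a neutrophil chemokine, had 98.8 CPM in the control of line 1 and 6250 CPM with the PHGDH guide there, against 1580 and 953 CPM in line 3. CD274, the PD-L1 gene, had 8.42 ± 0.89 and 13.1 ± 1.36 CPM (SD, n = 3), and 0 members passed when adjusted over the list alone.

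Markers of cell types went against the label in part: most endothelial markers were low, while most fibroblast markers were not. Of 29 endothelial identity genes, 2 averaged 10 CPM or more, ENG at 111 CPM and TEK at 12.4 CPM. KDR, the main VEGF receptor, stood at 19.9 and 20.7 CPM in line 1 and at 0 in the 4 libraries of lines 2 and 3. PECAM1 averaged 5.23 CPM, VWF 0.861 CPM and CDH5, the cadherin of endothelial junctions, 0.0862 CPM. Of 14 fibroblast markers, 10 averaged 10 CPM or more, among them COL1A2 at 2780 CPM and DCN at 144 CPM, and of 14 pericyte and smooth muscle markers 6 did, among them CSPG4 at 273 CPM and PDGFRB at 218 CPM. THY1, 1 of the 10 fibroblast markers, also differed by line. It stood at 103 and 65.5 CPM in line 1, 7.29 and 6.98 CPM in line 2 and 0 in line 3. FN1, the fibronectin gene, took 2.8% to 3.94% of all counts. Of 16 myeloid, 15 lymphocyte and 20 glioma, astrocyte and progenitor markers, 13, 12 and 13 averaged under 1 CPM, and EGFR at 472 CPM and NES at 97.8 CPM were the exceptions above 10 CPM in the last list.

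No cell type list was called by camera without the block. Adjusted p was 0.0771 for endothelial identity, 0.672 for pericytes and smooth muscle, 0.0837 for fibroblasts, 0.173 for glioma and astrocytes, 0.597 for myeloid cells and 0.402 for oligodendrocytes and neurons. Of 15 lymphocyte markers 3 were tested, too few for a list test, and 0 of them passed when adjusted over the list alone. With the replicate block the fibroblast list reached 0.0452 (adjusted p = 0.807 with block and an estimated correlation). ENG had 122 ± 6.70 and 99.7 ± 5.95 CPM and ANPEP, in the pericyte list, 256 ± 33.9 and 168 ± 22.3 CPM (SD, n = 3). Keratin and cornification genes were present in control line 1 and in the PHGDH-guide libraries of lines 2 and 3, with KRT6A at 11.1, 145 and 111 CPM there and at most 0.0767 CPM in the other 3 libraries.

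Ribosomal protein, mitochondrial and housekeeping genes had small medians over the 3 lines, with lines going opposite ways in the first 2 sets. Cytosolic ribosomal protein genes had a median log2 fold change of 0.09 over 32 members (camera adjusted p = 0.032 without and 0.0638 with the replicate block; adjusted p = 0.781 with an estimated correlation). Their median log2 ratio was 0.03, -0.09 and 0.34 in lines 1 to 3, with all 32 higher in line 3 and 29 lower in line 2. Without line 3 their direction turned to lower (adjusted p = 0.268), and without either library of line 3 the call was lost (up to 0.608). Mitochondrial genome mRNAs had adjusted p = 0.127, with all 13 lower in line 1 (median -0.35), all 13 higher in line 2 (0.28) and 11 lower in line 3 (-0.27). Housekeeping genes had a median of -0.02 with adjusted p = 0.386. In all, camera called 7 of 29 lists at the preset correlation, 6 lower and 1 higher, and 0 with an estimated correlation. The count was 4 without line 3 or either of its libraries, and 11 without line 1 or either library of line 2.

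**Figure D3:**
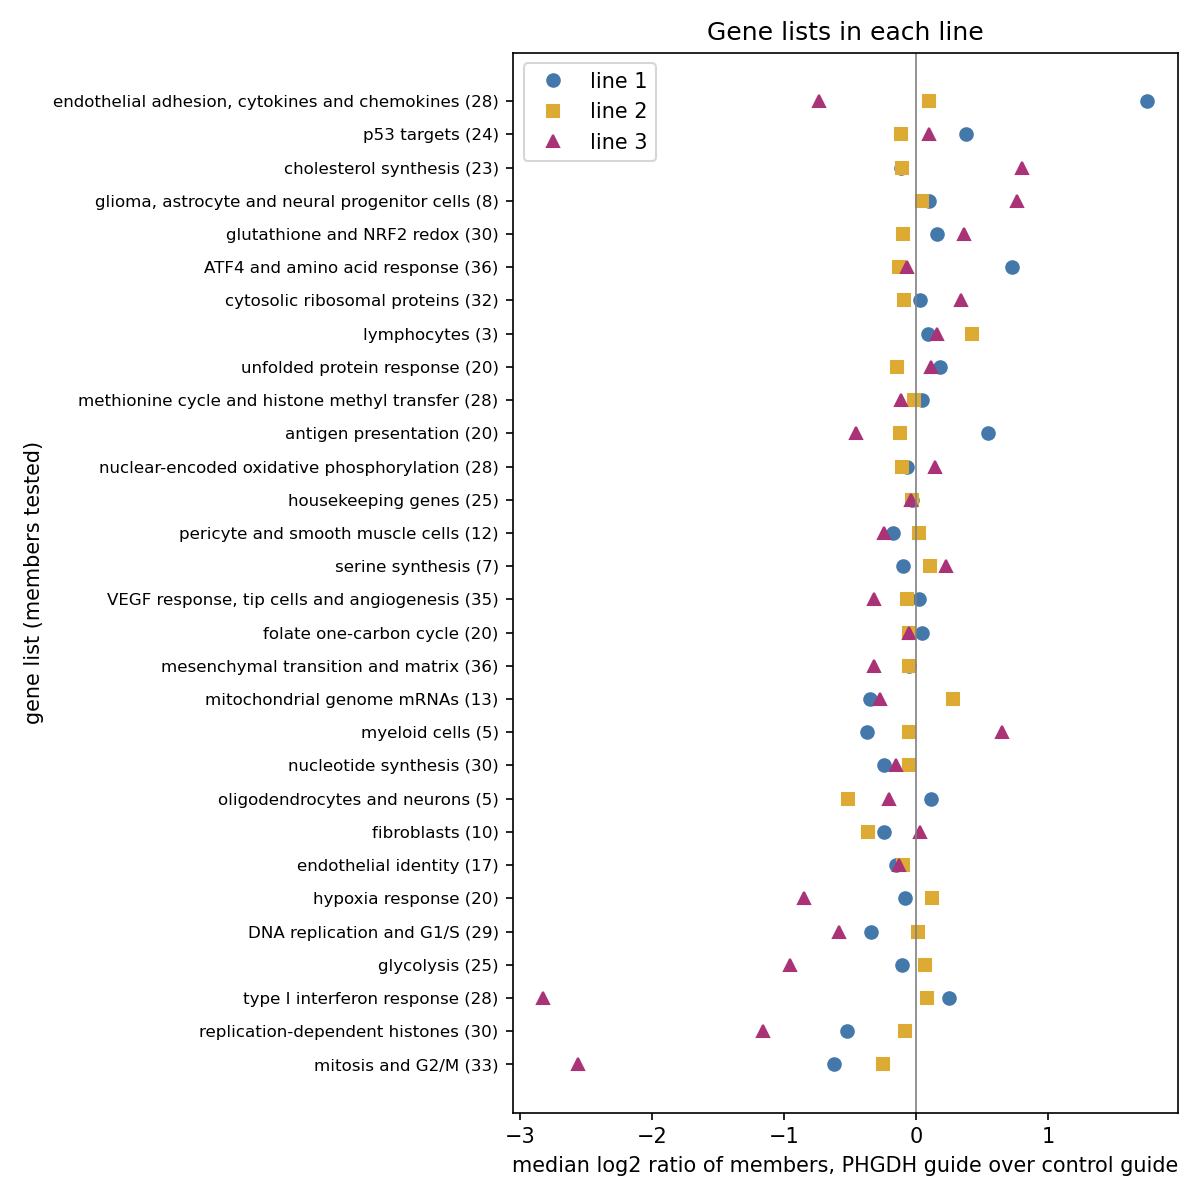
Median log2 ratio of PHGDH guide over control guide for the members of each gene list, in lines 1 to 3, with the number of tested members in brackets. Mitosis and G2/M genes lie at -0.62, -0.25 and -2.56, and the interferon list at 0.25, 0.08 and -2.82.

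With 1 library per guide in each line, a ratio between guides also holds any other difference between its libraries. The log2 ratios correlated across genes with Pearson r of -0.18 between lines 1 and 2, -0.08 between lines 1 and 3 and 0.13 between lines 2 and 3. Genes are not independent replicates. The sign was the same in all lines for 23.4% of genes, where chance gives 25%. The first principal component held 35.8% of the variance and the second 23.7%, and neither parted the guides or the lines. The first gave negative scores to the 3 libraries with keratin genes (control line 1 at -17.37, PHGDH lines 2 and 3 at -14.69 and -43.92). The other 3 had positive scores (PHGDH line 1 at 6.59, control lines 2 and 3 at 9.17 and 60.22), and line 3 held the largest. Libraries of a line deviate in opposite directions in most genes, so a component tends to part each pair, which only 4 divisions do. The second component also parted each pair, in another way. The match of the first is thus weak support for a division by keratin genes. The signs of the 3 Pearson correlations between lines are those a division by keratin genes would give. Spearman correlations were -0.123 between lines 1 and 2, 0.016 between lines 1 and 3 and 0.022 between lines 2 and 3. The sign for lines 1 and 3 thus turned, so the match depends on the measure used. The guide was not separated from this division.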

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

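All tests in this part were chosen after the results were seen, except that of squamous genes not looked at before. The cytokine and chemokine list moved in opposite directions between lines, with a median log2 ratio of 1.75 in line 1 and -0.73 in line 3, a gap of 2.48. That difference was not tested, since each line has 1 library per guide. A pair of squamous epithelium lists, written after keratin genes had been noticed, also moved in opposite directions between lines. The genes already seen had medians of 4.87 in line 2 and -4.46 in line 1, a gap of 9.33, and those not looked at before had 0.84 in line 3 and -1.81 in line 1, a gap of 2.65. Neither difference was tested.

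The keratin pattern included KRT6A (11.1, 145 and 111 CPM), KRT16 (9.52, 75.6 and 58.1 CPM) and S100A9 (9.97, 73.9 and 55.3 CPM) in control line 1 and PHGDH lines 2 and 3, each at 0.208 CPM or less in the other 3 libraries. A response to the PHGDH guide is argued against by the median log2 ratio of -4.46 in line 1, against 4.87 in line 2. RNA from squamous epithelial cells in 3 libraries may be the source: of 30 squamous genes not looked at before 7 were detected, and 57.1% of these followed the seen ones across libraries with r above 0.8, against 10.3% of 14181 other genes. No label names a sort that would remove such cells, and 4 of 7 genes is a small base. Leaving these 3 libraries out gave 0 genes and 8 lists, but 1 PHGDH-guide library then stands against 2 controls, assumed to vary like them, so neither count shows stability.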

How the results depend on the processing

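The alternatives were planned before the data were examined, except leaving out the 3 libraries with keratin genes and testing genes with reads in every line only, which were chosen after seeing the data. The count of 0 genes in edgeR stayed at 0 with the replicate block, DESeq2 size factors, either filter and genes with reads in every line only. It ranged from 0 to 0 when any line or library was left out, and was 0 without the keratin libraries (1 PHGDH-guide library against 2 controls), but a count of 0 cannot fall in a smaller design, so these show no stability. It was 1 with library totals (SLC7A2), 223 in DESeq2, 3 in DESeq2 with the replicate block (KCTD7, SLC7A2 and THBS1), 2 in limma-voom (KCTD7 and SLC7A2) and 6 at an adjusted p under 0.1, and the cause was not tested. The 7 called lists became 9 with the replicate block, 0 in camera with an estimated correlation, with or without the block, and 0 in the directional test of fry, with or without it. Fry's test for change in either direction called 4 lists without the block (endothelial identity, oxidative phosphorylation, methionine cycle, VEGF response) and 0 with it. They ranged from 4 to 11 when a line or library was left out, being 4 without line 3 or either of its libraries and 11 without line 1 or either library of line 2, and from 5 to 15 with the replicate block and a line left out. Without line 3, the type I interferon response, list test, turned to higher (adjusted p = 0.0822, or 0.108 with the block) and the cytosolic ribosomal proteins, list test, to lower (0.268, or 0.539 with the block). Over all left-out lines and libraries these adjusted p ranged from 2.34e-06 to 0.302 and from 9.4e-05 to 0.608. Mitosis, histone and DNA replication lists were called in 19 of 23 alternatives each, all but the estimated correlation and fry. The result for PHGDH in every library kept its direction in each fit, with log2 fold changes from -2.37 to -4.30 when a line was left out and -3.41 with the replicate block. Of 151 other named genes, 17 changed sign in 1 alternative or more. Depth limits low genes most in control line 3.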

Other observations

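The tests of metallothioneins, lysosomal genes, YAP targets, whole values, line differences and KCTD7 were chosen after the results were seen, and their gene lists are not independent evidence. Metallothioneins, small proteins that bind zinc and copper, were lower under the PHGDH guide. Of 6 tested members, 4 passed in edgeR when adjusted over the list alone, all lower, and 1 with the block, with a list p of 0.0133 in camera with an estimated correlation and 0.0458 with the block as well. MT1E had 173.5 ± 13.1 and 108.9 ± 8.998 CPM (SD, n = 3) with the control and the PHGDH guide and a log2 fold change of -0.67 ± 0.09 (SE), and MT2A had log2 ratios of -0.85, -0.06 and -1.24 in lines 1 to 3. Their sequences are similar, so reads can be divided between them.

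Lysosomal genes and targets of the MiT and TFE transcription factors had a median log2 fold change of 0.17 over 31 members, of which 10 were higher in all lines and 0 had p under 0.05 in the lower direction. Camera gave p = 3.52e-04 at the preset correlation and 0.109 with an estimated correlation. FLCN, 1 of its members, had log2 ratios of 0.54, 0.75 and 0.80. Of 22 YAP and TEAD targets, 5 passed in edgeR when adjusted over the list alone and 0 with the block, with camera p = 0.00724 at the preset and 0.0971 with an estimated correlation.

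In most genes the libraries of a line deviated from their guide means in opposite directions, with r of -0.72, -0.74 and -0.64. Whether the lines hardly differ in these genes cannot be judged from genes with 1 line at 0. There the difference between the other lines was alike under both guides, with r of at least 0.791, but those genes were picked for differing between lines. Removal of a line effect from the counts before deposit is a candidate explanation. Of genes with a line at 0, which a correction such as ComBat-seq skips, 86.2% hold values above 1 that are not whole. Of genes with reads in every line 0 do, and their 1009 values that are not whole are all at most 1. Over 13719 tested genes with reads in every line, the line held 11.5% of the variance, and the part left after line and guide 61.2%. Lines that do not differ would give 40% by chance for each. In these genes the values argue against lines that hardly differ as the whole explanation. The table is named as raw counts, which runs against removal. Counts simulated with line effects (SD of 0.7 log2, assumed) and no guide effect, then corrected with the guide kept, gave p under 0.05 for 19.3% of genes without the block and 4.56% with it, where the data gave 14.7% and 2.79%. With the guide not kept the shares were 23.7% and 17.8%, so the p-values without the block may be too small, and no biological explanation was tested.

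The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. In edgeR the real split gave 0 genes, which all 10 splits must reach, so that comparison says nothing. The highest other gave 25, and it sets the 3 libraries with keratin genes against the other 3. DESeq2 gave 223 genes in the real split and 407 in the highest other, with 3 splits at or above the real one, and camera 7 lists and 14, with 8 splits. The 4 splits that part all 3 pairs, the real one among them, gave 191 to 407 genes in DESeq2 and 1878 to 2604 genes with p under 0.05 in edgeR. The 6 splits that part 1 pair gave 0 to 6 and 3 to 23. With the replicate block, DESeq2 gave 0 to 32 genes over the 4 splits, against 3 for the guides. The split by keratin genes gave the 407 genes without the block and the 32 with it, more than the guides in both. The gene counts without the block thus follow the pairing of the libraries. Whether this comes from the samples or from processing of the counts, the splits cannot tell. The list counts do not, with 7 to 12 over the 4 splits and 0 to 14 over the 6.

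KCTD7 was at 0 in the control libraries and near 9.54 CPM with the PHGDH guide, where its values lay closer together than counting error would on average give. Reads moved from the neighbour RABGEF1 are argued against by its log2 fold change of 0.361 ± 0.126 (SE), where a loss was predicted, but only weakly: its log2 ratios were 0.38, 0.01 and 0.70 in lines 1 to 3, and with the block the SE was 0.174 (edgeR unadjusted p = 0.0826). Different gene models for the 2 groups are argued against too, since 1 gene, KCTD7 itself, was at 0 in a whole group and at 1 CPM or more in every library of the other. CRCP, a further gene of the region, had log2 ratios of 0.52, 0.57 and 0.53. A response to the guide stays open, and no biological explanation was tested.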
